A study of Capra hircus with 6 samples.

How the data were processed

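DNA methylation was sequenced in the ovaries of 6 Jining Grey goats (Capra hircus), 3 of a high fertility group and 3 of a low fertility group, which the labels define by the number of kids per birth. The labels give 1 library per sample and do not state that the samples are separate animals, though they are called animals here. P-values measure the spread between these samples, except those on reads pooled per group, the authors' among them. Those leave that spread out. Groups and replicate numbers came from the labels.

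The deposited sample files hold a coverage count for each cytosine and strand, with a minimum of 10 reads in all files. Per the file headers, they also hold the percent of reads that read C and the percent that read T at each cytosine, taken here as methylated and unmethylated. Coverage times percent lay within 0.235 of a whole number in every library, so methylated reads were recovered by rounding. A lambda phage DNA contig in each file served as a control for conversion of unmethylated cytosine and was left out of all other values. The aligner, the caller, the conversion chemistry and the genome build are not given in the sources used here. The submitters' processing notes name bedtools 2.25.0.

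The authors' deposited table lists 61299 tiles of 1000 bp that overlap annotated features, each with a difference, a p-value and a q-value. Recomputed from the deposited sample files, the authors' difference equalled the mean percent of the high group minus that of the low group, which gives its direction. The deposited p-value equalled, for 100% of tiles within 1e-06 on the log10 scale, a likelihood ratio test on reads pooled per group with no term for the animals. In the authors' deposited table the smallest absolute difference is 10.00006 points and the largest q-value is 0.49998.

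Reads of all CpGs were summed in 1000 bp tiles, and 1910971 tiles with at least 10 reads in each of the 6 samples were tested. The median was 109 reads per tile and sample. The main test was the edgeR 4.0.16 quasi-likelihood test on methylated and unmethylated reads (R 4.3.3), with a common dispersion and total reads as library size; adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Log2 values are log2 odds ratios of methylation, high over low fertility. The alternative test was limma 3.58.1 on log2 ratios of methylated to unmethylated reads.

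No gene coordinates on the files' build were used here, so the promoter and gene body windows planned before the data were examined were replaced. Promoters are tiles that the authors' deposited table annotates as TSS, judged by the adjusted p over all tiles; these tiles were listed because their difference exceeded 10 points. Gene bodies are gene interiors: all covered tiles strictly between the first and last tile the authors' deposited table assigns to a gene symbol, with at least 5 tiles, which gave 4759 genes. An interior can be shorter than the gene, and only genes with listed tiles have one. Of 8142 gene symbols in the authors' deposited table, 7694 matched symbols of the RefSeq annotation of assembly ARS1.2, which was used for names and for which genes lie on X.

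Single values per sample were compared by exact permutation tests, two-sided, whose smallest p for 3 against 3 is 0.1. Gene lists were fixed before the data were examined and tested on gene interiors by camera with a preset correlation, by camera with an estimated correlation and by fry. Promoter values were not used for list tests because those tiles were selected on their difference. Interiors exist only for genes with listed tiles, so the list tests are not free of that selection either. The genes named are, for tiles, TSS tiles and gene interiors, the 5 with the smallest p in each direction whose groups did not overlap, skipping those without a symbol. For each list they are the members that passed over the list alone or else the 2 with the smallest p. A fixed set of fertility, imprinting and methylation genes is named wherever measured.

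The edgeR and limma steps were tested on simulated reads with the real coverages and a single spread between animals, the median of the real data. Real features differ in spread, so the recoveries hold for features of that median spread. All simulated changes were decreases in low fertility. Of 50 changed tiles per size, among 1910971 tiles, edgeR recovered 0% at 10 points, 18% at 20 points, 94% at 40 points and 100% at 60 points. Of 50 changed gene interiors per size, among 4759, it recovered 8% at 2 points, 76% at 5 points and 100% at 10 points. Limma recovered 0% of the tiles at 20 points, 14% at 40 points and 74% at 60 points, and 12%, 64% and 100% of the interiors at 2, 5 and 10 points. Among the features left unchanged, edgeR called 5 tiles and 7 interiors, and limma called 1 tile and 15 interiors.

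Alternatives tried were limma, a minimum of 20 reads, each sample left out, the replicate number as a block, other tile sizes and other adjusted p thresholds. Added after seeing the data were CpGs covered in all 6 samples, the pooled-read test, a dispersion estimated per tile and centring of each library. Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6 were used for the remaining steps.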

Results

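Methylation was measured at single cytosines in the ovaries of 6 Jining Grey goats, a Chinese breed known for large litters, to ask whether ovarian DNA methylation differs between goats of high and low fertility. The files covered 11223139, 17204434 and 10845830 CpGs in high fertility 1, 2 and 3, and 12327278, 10725329 and 7551847 in low fertility 1, 2 and 3. Reads on cytosines ranged from 153685663 in low fertility 3 to 333845626 in high fertility 2, and the median coverage ranged from 13 to 20 reads. Between 0.104% and 0.124% of reads on the lambda control were called methylated. Across 6096470 CpGs covered in all samples, levels correlated between samples with Pearson's r from 0.764 to 0.806, across CpGs, which are not independent replicates.

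The methylation level of the ovarian genome did not differ detectably between the groups. The level over all covered CpGs was 72.9% ± 0.233 (SD, n = 3) in high fertility and 72.1% ± 1.14 (SD, n = 3) in low fertility, a difference of 0.781 points (exact permutation test, two-sided, p = 0.4). Low fertility 3 had the lowest level, 70.8%, while low fertility 1 had the highest, 73.1%. Scaffolds LWLT01000021.1 and LWLT01000027.1, on which 115 of 115 and 60 of 60 matched genes are X-linked in assembly ARS1.2, were less methylated than the autosomes in all 6 samples. Together they were at 63.0% ± 1.16 (SD, n = 3) in high and 61.7% ± 1.92 (SD, n = 3) in low fertility, against 73.5% ± 0.241 and 72.7% ± 1.11 on the 29 autosomes. Gene interiors were at 77.4% ± 0.219 in high and 76.6% ± 0.778 in low fertility, the difference of 0.749 points having p = 0.2 in the exact permutation test. Of 38 chromosomes, scaffolds and tile classes, 36 had a higher mean in high fertility, and none passed after adjustment, which this design cannot reach. Without low fertility 3 the genome-wide difference was 0.162 points.

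**Figure D1:**
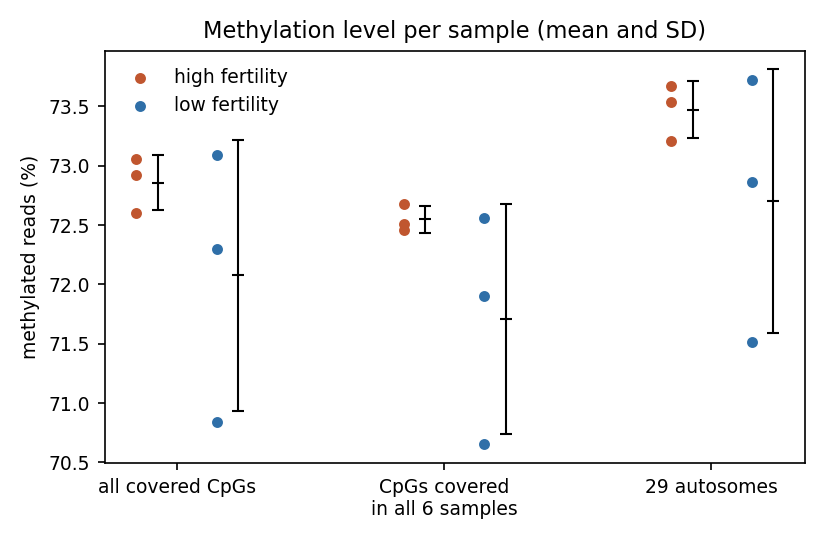
Methylation level of each sample (points, percent of methylated reads) with the mean and SD of each group, over all covered CpGs, over CpGs covered in all 6 samples and over the 29 autosomes. Low fertility 3 lies lowest, at 70.8% over all covered CpGs.

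At single regions, the most separated tiles in named genes lay in introns of CACNA2D3, UBQLN1, WDFY3, FOCAD and DLG1, all more methylated in high fertility, and in POSTN, EHHADH, PLA2G4A, ADAMTS7 and PRPF39, all less methylated there. None of these passed the threshold. The tiles held from 2 CpGs in POSTN and 3 in UBQLN1 and EHHADH to 11 in CACNA2D3, so some values rest on few CpGs. The tile of CACNA2D3, a calcium channel subunit, on chromosome 22 from 46723001 to 46724000 was at 85.1% ± 1.24 in high and 18.5% ± 10.3 in low fertility (SD, n = 3), on 67 to 208 reads per sample (edgeR adjusted p = 0.171). An intronic tile of UBQLN1, a ubiquilin, on chromosome 8 from 76671001 to 76672000 was at 88.6% ± 0.653 and 38.8% ± 2.72 (edgeR adjusted p = 0.210). WDFY3, which acts in selective autophagy, differed by 32.6 points, FOCAD by 25.9 points and DLG1, a cell polarity scaffold, by 30.4 points. An exonic tile of POSTN, the matrix protein periostin, on chromosome 12 from 62422001 to 62423000 was at 0% in all high fertility samples and at 28.7% ± 7.60 in low fertility (edgeR adjusted p = 0.445). The difference was -45.1 points in EHHADH, a peroxisomal enzyme, -27.8 points in PLA2G4A, a phospholipase that releases arachidonic acid, -26.8 points in ADAMTS7 and -26.1 points in PRPF39. Before these, 9 tiles without a symbol in the higher direction and 27 in the lower direction were skipped.

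Of 1910971 tiles, 0 passed edgeR's test after adjustment, with a smallest adjusted p of 0.122 for a tile in an intron of an unnamed gene on chromosome 1. At an unadjusted p under 0.05, edgeR had 84907 tiles, 4.44% of all, and limma had 18 tiles after adjustment, 12 of them higher in high fertility. In all 18 tiles of the limma test, 1 group was at 0% in each of its samples, and none held more than 6 CpGs. Among them are an intronic tile of SERGEF (3 CpGs) and a tile over coding exon and intron of RABGAP1L (1 CpG). Both are named here after their values were seen. The groups did not overlap in 10.02% of tiles, and chance gives 10%. Among 235853 tiles differing by more than 10 points, 62.7% were higher in high fertility, and 52.5% when each library was centred on its own mean.

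The authors' deposited table lists 37523 tiles with higher and 23776 with lower methylation in high fertility. PCDH15, with 156 tiles, CACNA2D3, with 116, and FSTL5, with 111, have the most tiles in the authors' deposited table. Of the tiles in the authors' deposited table, 38515 have a q-value under 0.05 in the pooled-read test, 0 passed the edgeR test after adjustment, and 19607 had an unadjusted edgeR p under 0.05. The groups did not overlap in 36.6% of them, tiles that were chosen for their difference.

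At transcription start sites, the most separated tiles higher in high fertility belonged to UBR3, ABCA5, C20orf202, OR2AE1 and FGF2, and those lower belonged to DYNC2LI1, SYT14, CCDC28B, DLX3 and SEC22B. The tile of FGF2, a growth factor, on chromosome 17 from 36226001 to 36227000 was at 41.2% ± 2.01 in high and 14.0% ± 5.47 in low fertility (SD, n = 3; edgeR adjusted p = 0.737). UBR3, a ubiquitin ligase, was at 93.3% ± 4.33 and 41.0% ± 6.05 in a tile with 2 CpGs. ABCA5, a lipid transporter, was at 65.1% ± 6.65 and 2.30% ± 3.98, on 11 to 259 reads. C20orf202 differed by 69.5 points on as few as 10 reads in a sample, and OR2AE1, an olfactory receptor, by 41.9 points. The tile of DYNC2LI1, a ciliary motor subunit, was at 2.97% ± 2.72 in high and 24.6% ± 3.84 in low fertility. The difference was -29.0 points in SYT14, -19.7 points in CCDC28B, -29.9 points in DLX3 and -61.6 points in SEC22B, where high fertility 3 was at 0%, the others of its group at 44.4% and 47.2%, and a sample had as few as 12 reads. STAR, the carrier that delivers cholesterol for steroid synthesis, had a start site tile on chromosome 27 from 12351001 to 12352000 at 15.1% ± 8.36 in high and 42.2% ± 12.6 in low fertility, on 11 to 213 reads (edgeR adjusted p = 1). CYP19A1, or aromatase, had 2 start site tiles among its 5 listed tiles. Of those 5, 3 were higher and 2 lower in high fertility, and 0 had an unadjusted edgeR p under 0.05.

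Of 3795 start site tiles in the authors' deposited table, 1958 are higher in high fertility and 1837 lower. None passed by edgeR (0 tiles, smallest adjusted p 0.445) or by limma (0 tiles), and 1071 had an unadjusted edgeR p under 0.05. In the lower direction 12 tiles without a symbol were skipped.

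Over whole gene interiors, GLRB and MCM6 were the genes closest to the threshold, both more methylated in high fertility. GLRB, the beta subunit of the glycine receptor, on chromosome 17 from 28966001 to 29072000, was at 77.7% ± 0.813 in high and 70.8% ± 3.18 in low fertility (SD, n = 3), a log2 odds ratio of 0.52 ± 0.09 (SE; edgeR adjusted p = 0.0719). MCM6, a subunit of the replicative helicase, on chromosome 2 from 74711001 to 74737000, was at 83.8% ± 2.28 and 76.2% ± 3.11, a log2 odds ratio of 0.69 ± 0.13 (SE; edgeR adjusted p = 0.0802). RRM2B, a ribonucleotide reductase subunit, was 6.09 points higher in high fertility, FSD1L 3.92 points and TRDC, the constant region of a T cell receptor, 9.64 points. In the other direction, the difference was -10.9 points in ZNF274, a zinc finger protein, -3.23 points in TOM1L1, -7.93 points in KLKB1, which encodes plasma kallikrein, -6.57 points in KIAA0513 and -3.96 points in ZNF215. The difference in ZNF274 turned to a log2 odds ratio of 0.15 at the CpGs covered in all 6 samples, where that of TOM1L1 fell from -0.33 to -0.15. Without high fertility 2 the value of ZNF274 fell from -0.89 to -0.55, and that of KLKB1 fell from -0.58 to -0.36 without high fertility 3.

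Of 4759 gene interiors, 0 passed edgeR's test after adjustment and 0 passed limma's. At an unadjusted p under 0.05, edgeR had 343 interiors, 316 of them higher in high fertility, and limma had 299; without low fertility 3 edgeR had 205, and without low fertility 1 it had 585. GLRB passed without high fertility 1, without high fertility 2 and without low fertility 1, and MCM6 passed without high fertility 1 and without low fertility 1. Those fits called 2, 2 and 9 interiors by edgeR's adjusted p. Without low fertility 3 their edgeR adjusted p was 0.347 and 0.529, without low fertility 2 it was 0.164 for both, and in the limma test 0.561 for both. Both genes passed with the replicate number as a block, and MCM6 at the CpGs covered in all 6 samples. The groups did not overlap in 13.5% of interiors, against 10% by chance for genes not chosen for a difference, whereas interiors exist only for genes with tiles listed for theirs.

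**Figure D2:**
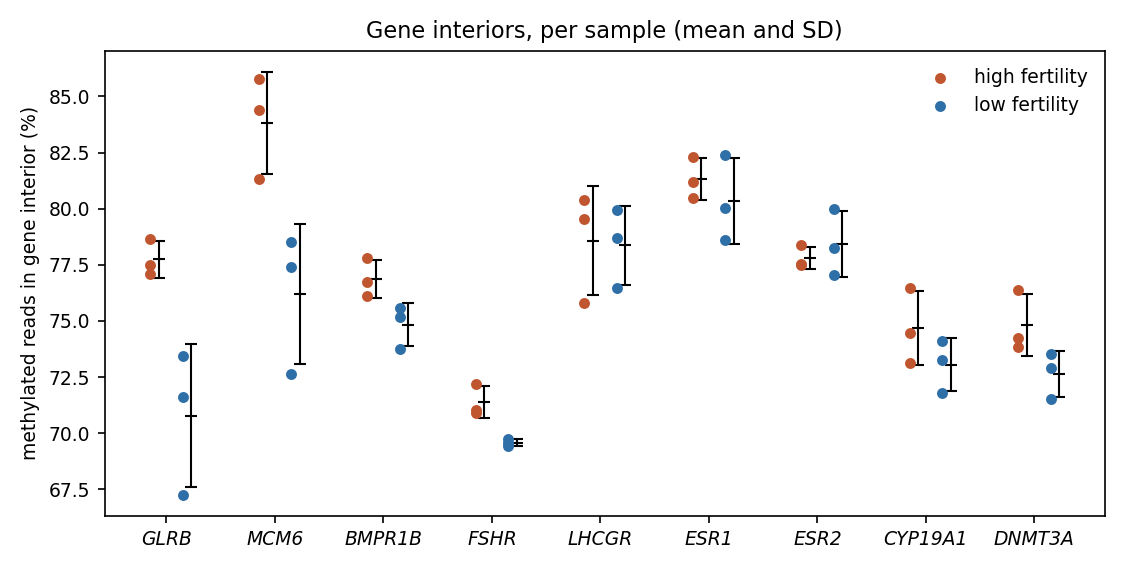
Percent of methylated reads in the interiors of 9 genes for each sample (points), with the mean and SD of each group (n = 3). GLRB and MCM6 were named by a rule that asks for groups that do not overlap. The groups also lie apart in BMPR1B, FSHR and DNMT3A, while those of ESR1, ESR2, LHCGR and CYP19A1 overlap.

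Among genes known for litter size and ovarian function, the interior of BMPR1B, the receptor whose variant raises ovulation rate in sheep, was at 76.9% ± 0.845 in high and 74.8% ± 0.964 in low fertility (SD, n = 3), with no overlap (edgeR adjusted p = 0.603). FSHR, the receptor for follicle stimulating hormone, was at 71.4% ± 0.709 and 69.6% ± 0.149, also without overlap (edgeR adjusted p = 0.674). The interiors of ESR1 and CYP19A1, the estrogen receptor alpha and aromatase, differed by 0.974 and 1.63 points, and those of ESR2 and LHCGR by -0.623 and 0.205 points. DNMT3A, a DNA methyltransferase, differed by 2.17 points, also without overlap. Without low fertility 3 the log2 odds ratio of ESR1 fell from 0.09 to 0.01 and that of ESR2 turned from -0.05 to 0.01. Without low fertility 1 the log2 odds ratios moved the other way, to 0.18 in ESR1 and -0.11 in ESR2. Without high fertility 2 those of CYP19A1 and DNMT3A fell from 0.13 to 0.06 and from 0.17 to 0.10, and that of LHCGR turned from 0.02 to -0.06, turning also without high fertility 3 and without low fertility 3. At the CpGs covered in all 6 samples ESR2 turned to 0.04 and LHCGR to -0.01. BMP15, an oocyte growth factor, had 1 tile in the authors' deposited table, on scaffold LWLT01000021.1 from 15300001 to 15301000, at 55.4% ± 10.6 in high and 69.4% ± 4.85 in low fertility. A tile at the end of GDF9, its partner in the oocyte, was at 79.95% ± 4.22 and 68.8% ± 1.87, and a tile of INHA, the inhibin alpha subunit, at 79.8% ± 13.8 and 68.2% ± 17.9. None of these tiles passed (edgeR adjusted p = 1). AMH, IGF2, H19 and DNMT1 have no tile under these symbols in the authors' deposited table and were not analysed here.

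None of the 12 gene lists passed the test as a group. Only members with a gene interior were tested, from 6 of 33 imprinted genes to 17 of 27 hormone receptors. The counts below are of these tested members, not of whole lists. Camera gave an adjusted p of 0.983 for each list, and 0.985 with an estimated correlation, and fry's smallest adjusted p was 0.667 for a shift in 1 direction and 0.315, for the endothelial list, for changes in either direction. Over all 4759 interiors 3481, or 73.1%, were higher in high fertility, a share to hold beside the counts of each list. No member of any list passed edgeR over all genes or adjusted over the list alone. On the TGF-beta list 13 of 18 tested members were higher in high fertility, among them BMPR1B and B4GALNT2 (4.40 points). B4GALNT2 was on this list but is not itself a TGF-beta ligand, receptor or antagonist. Of the hormone receptors 16 of 17 were higher, FSHR and LEPR, the leptin receptor (1.99 points), having the smallest p. Of the steroid synthesis genes 3 of 9 were higher, with HSD17B4 at 1.21 points beside CYP19A1, and the list's median of -0.0873 and mean of 0.0980 points differ in sign. Of the granulosa, theca and ovulation genes 6 of 10 were higher, led by KITLG, the KIT ligand (2.31 points), and PAPPA, a protease of IGF-binding proteins (1.27 points). Of the oocyte genes 7 of 9 were higher, including PIWIL2 (1.36 points) and NLRP14 (1.56 points). Of the follicle survival genes 3 of 5 were higher, with FOXO1 at 2.51 points and TP63, which guards oocytes, at a log2 odds ratio of 0.07. Of the imprinted genes 5 of 6 were higher, with KCNQ1 at 1.42 points and ZFAT at 1.64 points, and of the methylation machinery 4 of 7, with UHRF2 at 1.25 points beside DNMT3A. Among markers of other cells, 5 of 8 endothelial genes were higher, with PROX1 at 6.22 points (edgeR p adjusted over the list alone 0.0536) and PECAM1 at 2.12 points. All 4 immune genes were higher, ITGAM by 2.63 and PTPRC by 0.861 points, and 4 of 5 muscle and fibroblast genes, with MYH11 at 3.85 and MYOCD at 1.02 points. Of 3 epithelial genes 2 were higher, EPCAM by 1.37 and CDH1 by 1.23 points. Several of these values lean on 1 sample, in either direction. The log2 odds ratio rose to 0.64 in MYH11 without high fertility 1 and to 0.28 in ITGAM without high fertility 3. It rose to 0.18 in PAPPA without low fertility 1 and to 0.18 in UHRF2 without low fertility 2. Without low fertility 3 the log2 odds ratio turned from 0.07 to -0.01 in TP63, from 0.07 to -0.02 in PTPRC and from 0.16 to -0.0034 in KITLG, and it fell to 0.00 in MYOCD, 0.01 in NLRP14, 0.03 in PAPPA and 0.05 in ZFAT. Without high fertility 2 it fell from 0.34 to 0.06 in MYH11, from 0.13 to 0.03 in LEPR, from 0.16 to 0.08 in ITGAM and from 0.10 to 0.06 in PIWIL2. Without high fertility 1 it turned to -0.02 in EPCAM and -0.01 in CDH1 and fell to 0.09 in HSD17B4, without low fertility 2 it turned to -0.01 in EPCAM, and without low fertility 1 it fell to 0.01 in UHRF2. At the CpGs covered in all 6 samples it fell to 0.12 from 0.23 in FOXO1, to 0.05 in NLRP14, to 0.07 in PIWIL2 and to 0.10 from 0.15 in PECAM1, and rose to 0.24 in CDH1, 0.20 in EPCAM and 0.12 in MYOCD. The differences in points lie beside a median difference of 0.690 points over all interiors.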

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

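The pooled-read, per-tile dispersion, centring and CpG-set alternatives, the other adjusted p thresholds for gene interiors and the leave-one-out shares were chosen after seeing the data. Against 0 tiles in the edgeR test, limma called 18, 500 bp tiles 5, CpGs covered in all 6 samples 4 and a dispersion per tile 3. Reads pooled per group gave 204269 tiles, or 127440 with at least 10 points. The cause of these differences was not settled, and pooling leaves out the variation between animals. Leaving out 1 sample, 20 reads, 5000 bp tiles and thresholds of 0.01 and 0.1 left 0 tiles, and every setting run on start site tiles gave 0. Gene interiors went from 0 to between 0 and 9 without 1 sample, to 2 at an adjusted p under 0.1, and to 1 at CpGs covered in all 6 samples. Deviations of samples with the same replicate number correlated at -0.0529, -0.00574 and 0.0748. Those with different numbers correlated at -0.101 to 0.119. With 3 samples per group, these values cannot settle whether the numbers pair the samples. With the replicate block, gene interiors passing were 2, tiles 0, lists 0, and the global difference 0.781 points. That difference lay between 0.162 and 1.29 points without 1 sample. The share of tiles higher in high fertility lay between 54.8% and 66.3% without 1 sample, lowest without low fertility 3, next lowest, 56.8%, without high fertility 2, and was 52.5% after centring. Without 1 sample, log2 odds ratios changed sign in 7 named interiors that did not pass, ranging from -0.023 to 0.32 for EPCAM, -0.0095 to 0.16 for CDH1, -0.012 to 0.15 for TP63, -0.0034 to 0.36 for KITLG, -0.016 to 0.12 for PTPRC, -0.11 to 0.012 for ESR2 and -0.062 to 0.13 for LHCGR. At CpGs covered in all 6 samples they were 0.15 for ZNF274, 0.035 for ESR2 and -0.0072 for LHCGR, each the opposite of the main sign; the cause was not tested. A coverage minimum below 10 changes nothing in these files; other promoter windows and alternatives for other data types were not run.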

Other observations

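All tests in this part were chosen after the results they bear on were seen, except the test of neighbouring CpGs against those spanning 20 to 40 points, and the bound of the test on conversion of methylated cytosine, 50% at first, was restated after its values were seen. The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The edgeR test called 0 tiles and 0 gene interiors for the fertility groups, where the highest of the other splits were 0 and 1; with a count of 0 all 10 splits give as many whatever the data, so those counts test nothing. At an unadjusted p under 0.05, 84907 tiles stood against a highest other of 116171, with 4 splits at least as large. For gene interiors 343 stood against 492, with 2 splits at least as large. Both counts of splits include the fertility split itself.

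The pooled-read test, whose p-values equal those in the authors' deposited table, gave 127440 tiles past an adjusted p of 0.05 and 10 points. Other splits of the same animals, each mixing the fertility groups, gave from 105123 to 162219. Of the 10 splits, 4, the fertility split counted, gave at least as many. Counts near that of the fertility split thus also arose from groupings other than fertility. Within groups, the variance between samples, read sampling included, was a median of 1.88 times that of read sampling alone. When each tile's own dispersion was used, 3 tiles passed. That test has few degrees of freedom, so few tiles could pass whatever the cause, and its count does not tell causes apart. From the variance ratio, variation between animals of a group is a candidate explanation for part of these tiles, in a share left open. A difference tied to fertility remains open.

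Low fertility 3 had the lowest methylation, and the share of tiles higher in high fertility, 62.7% of those differing by more than 10 points, was 54.8% without it, though also 56.8% without high fertility 2. A difference in the conversion of unmethylated cytosine is argued against by the lambda control, whose methylated share differed by at most 0.0115 points from any other library. Coverage of different CpGs is argued against too, since at the CpGs covered in all 6 samples it stayed 1.25 points below the next lowest. Conversion of methylated cytosine would lower each level in proportion to itself, giving tiles at 85% or above a shortfall of 199% of that in tiles of 30 to 50%, but it was 17.4% and 53.0% against the other low fertility samples. A loss of methylated reads, which lowers middle levels most, stays open, as do cell makeup, age and cycle stage of the ovary, all untested, and the other low fertility samples, at 73.1% and 72.3%, do not share the low level.

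At 264793 of the CpGs covered in all 6 samples, 4.34%, the level spanned over 60 points between animals. The hypothesis was that many of these are C to T or G to A sequence variants of single CpGs, which would leave the neighbouring CpG unaffected. The neighbour taken was the next CpG downstream covered in all 6 samples, where it lay within 50 bp. Such a neighbour existed for 72581 of these CpGs. Its deviation followed that of the CpG with a slope of 0.107 ± 0.00118, which is 13.0% of the slope at CpGs spanning 20 to 40 points. The error is a bootstrap SE over CpGs, which are not independent, and does not measure the spread between animals. That percentage met the bound set beforehand for variants, a corrected slope under 50% of this reference. Uncorrected for read sampling, on which the reference slope of 0.828 leans, the percentage was 42.3%. Against CpGs spanning 40 to 60 points, a reference added afterwards with a slope of 0.200, it was 53.5%, or 64.9% uncorrected. The slope thus falls with the span in steps, and how far sequence variants may account for differences at single CpGs, or in tiles with few CpGs and a group at 0%, such as that of POSTN, stays open without genotypes.

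High fertility 2 covered more of the genome than the rest, most of all where CpGs are dense. It covered 96.6% of tiles with 1 to 5 CpGs, against 75.5% to 87.6% in the other libraries, and 98.9% of tiles with 40 or more CpGs, against 26.1% to 64.5% in the other libraries, with a mean coverage of 15.5 reads at the CpGs covered in all 6 samples against 19.8 to 29.6. In the tiles of this density covered in all 6 samples its level was 65.0%, against 72.2% to 74.3%. Lambda reads made up 4.33% of its reads and 0.866% to 1.37% of those of the others.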
